A study of Homo sapiens with 6 samples.

How the data were processed

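MCF7 cells stably infected with lentiviral control vector or RBP2 vector were sequenced as poly(A)-selected, strand-specific libraries, 3 per group, per the labels. The groups and the replicate numbers came from the sample titles. The labels call the samples biological replicates but do not say how the cultures were kept apart, so p-values measure the spread between these samples.

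The values used were normalized FPKM, deposited by the authors as 1 table of 24332 loci with locus identifiers and gene symbols. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5, Cufflinks 2.2.1 and genome build hg19, without stating their roles, and the method of the normalization between libraries is not given in the sources used here. FPKM relates fragments to transcript length and to the library total, so it depends on composition, and where many abundant transcripts fall, others are raised. The sums of FPKM differed between libraries, from 536105 to 913945. Median-of-ratios factors of the deposited values lay between 1.00 and 1.02, so the typical gene was already level between libraries. Median-of-ratios scaling, 1 of the alternatives, could therefore change little. All 6 sample columns were used, and 546 rows name several genes. In total 402 symbols stand on more than 1 row, HLA genes among them, and stayed separate genes.

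The depth in reads is not given in the sources used here. Low FPKM values were searched for whole steps, and 2750 of 4619 loci with a mean below 0.9 FPKM (59.5%) held whole multiples in every library with a tolerance of 0.05 reads, too few to test counts. The steps gave the relative weight of 1 fragment per library. They also served to set the difference between pairs of libraries against counting noise. For RBP2 libraries 1 and 2 the variance over 1203 low loci was 1.27 times that of counting (chi-square p = 5.2e-10), where simulated counts with no difference gave 1.09; so a small difference beyond counting noise was found. For more abundant loci, the pair stayed at 1.15 to 1.47 times and every other pair of the same group rose to at least 22.6 times. These libraries were therefore averaged on the FPKM scale and treated as 1 sample. The design fixed before the data were examined had all 6 libraries as separate samples. The averaging was chosen after the values, and after the number of calls under both choices (4834 and 6833) had been seen; it gives the lower number.

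Loci with a mean of at least 0.5 FPKM over the 6 libraries were kept (12419), and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a trend, for group only, two-sided. A Benjamini-Hochberg adjusted p below 0.05 is a call. The pseudocount understates the change of low genes. Gene lists, 30 in all and fixed before the data were examined, were tested with camera from limma with a preset correlation of 0.01 for lists with at least 3 tested members, and again with an estimated correlation; 581 of 613 list entries were found. After the table had been seen, KMT2A, KMT2C, SC5D and TIGAR were matched through the older symbols MLL, MLL3, SC5DL and C12orf5. A symbol on several rows stands for the row with the highest mean.

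The named genes followed a rule fixed before the data were examined. It took KDM5A, KDM5B, KDM5C and RBP2; the 12 rising and 12 falling called genes with the largest log2 fold changes whose 3 RBP2 values all lay on 1 side of the control values and whose higher group mean was at least 2 FPKM; up to 4 called members of each list with the smallest p, or 2 members if none was called; and IGF1R, ERBB2, ERBB3, EGFR, ESR1, PGR, GREB1 and TFF1. Unnamed rows and genes of the sex chromosomes named in the rule were left out. STAT1, OASL, IFI27, IFITM2, IFITM3, TMEM173, CCNE2, CENPE, MKI67, COX6C and IGFBP4 are named as further list members, chosen after their values were seen.

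Transcript GC content and length came from GENCODE transcript sequences of a later genome build, matched by symbol, for 11244 of the tested genes (90.5%). No coordinates were taken from it. After the trends had been seen, each library's deviation from the gene mean was fitted on GC content and log2 length by loess (degree 1, span 0.3), and the residuals were tested again. Trends of this kind follow the groups here, so the correction also removes any real difference tied to GC content or length.

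The limma and camera steps were tested on simulated data. For control against RBP2 with 12419 genes, 50 genes each were given simulated log2 changes of 0.5, 1, 2 and 4. The shares called were 6%, 74%, 98% and 100%, with 10 false calls among 149. The noise was independent for each gene and held no trend of a library, so this is not the false-call rate in the data. With a simulated GC and length trend over 11244 genes, 812 false calls arose without the correction and 7 with it. The added trend was itself a loess fit to the data with the settings of the correction, so its removal was built in. The 7 false calls therefore cannot show whether the correction removes the trend of the data in full. Camera called the 1 shifted list only, with noise drawn independently for each gene. In the data the estimated correlation within lists reached 0.60 (cytosolic ribosomal proteins). The simulation therefore cannot vouch for camera p-values with the preset correlation. The simulated changed genes were drawn outside the lists, a revision made after a first version had called lists that were not shifted.

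Alternatives fixed before the data were examined were other pseudocounts, filters, scalings and variance models, a replicate block, summed rows of 1 symbol and each library left out. Added after the data were examined were the 6 libraries separate, RBP2 libraries 1 and 2 left out together, the GC and length correction alone and with the block or with control library 1 or 3 left out, and the genes with an annotation only. Figures and pair statistics used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.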

Results

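MCF7 is an estrogen receptor-positive human breast cancer cell line. Gene expression was measured by stranded poly(A) RNA sequencing in MCF7 cells carrying a stably integrated lentiviral construct for RBP2 or a control vector. The cells were measured after 48 h in medium without phenol red and with serum. RBP2 is read here as retinoblastoma-binding protein 2, a histone H3 lysine 4 demethylase whose gene is now called KDM5A. The deposited table held normalized FPKM (fragments per kilobase of transcript, relative to the library total) for 24332 loci in 3 control and 3 RBP2 libraries, described by the labels as biological replicates. The summed FPKM was 686095, 762777 and 913945 in control libraries 1, 2 and 3, and 542233, 536105 and 549810 in RBP2 libraries 1, 2 and 3. Read counts per library were not analysed here. From the steps of low FPKM values, the weight of 1 fragment in the other libraries was between 0.979 and 1.29 times that in RBP2 library 1, after the authors' normalization. RBP2 libraries 1 and 2 differed by little more than counting noise. Their variance was 1.15 to 1.47 times that of counting over 5 abundance classes, whereas the other pairs of the same group reached 22.6 to 87.9 times in the most abundant class. They were averaged and counted as 1 sample, which left 3 control and 2 RBP2 samples. That choice was made after the data were examined, and the counts with the 6 libraries kept separate are given with those of the 5 samples, for all genes tested and for each gene list. Gene positions were not analysed here.

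The comparison asked what changed in MCF7 cells when RBP2 was overexpressed. KDM5A (locus XLOC_005213) stood at 1.39 ± 0.082 FPKM (SD, n = 3) in the control libraries, with 1.34, 1.49 and 1.36 FPKM in libraries 1, 2 and 3. It was 126 FPKM in RBP2 library 1, 125 in RBP2 library 2 and 26.5 in RBP2 library 3, so that the first pair held 4.75 and 4.71 times the level of the third. The log2 fold change was 4.62 (SE 0.55, limma with Benjamini-Hochberg adjusted p = 0.0048), on the scale of log2(FPKM + 1), as are all log2 fold changes below. KDM5B, a paralog, had a log2 fold change of 0.14 (SE 0.15, adjusted p = 0.47), which turned to -0.29 (adjusted p = 0.076) after a correction for GC content and transcript length and to -0.27 (adjusted p = 0.029) with that correction and the 6 libraries separate, where it was called. KDM5C had a log2 fold change of 0.034 (SE 0.14, adjusted p = 0.86). KDM5A was thus the 1 called gene of the 3 in the KDM5 list, over all genes tested, adjusted over the list alone and with the 6 libraries separate (camera adjusted p = 0.33). The gene whose official symbol is RBP2, for retinol-binding protein 2, was listed at 0 in 5 libraries and at 0.133 FPKM in RBP2 library 3.

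The 12 named genes with the largest increases in RBP2 cells included 6 of the list of interferon-stimulated genes, namely IFIT2, SAMD9, RSAD2, IFIT3, IFI44 and SAMD9L. Of 12419 genes tested with limma, 4834 were called at an adjusted p below 0.05, of which 2375 rose and 2459 fell. With the 6 libraries kept separate, 6833 were called, 3286 rising and 3547 falling. In each of the 4834 called genes the RBP2 samples lay on 1 side of the control samples, which a call itself favours. The same held for 68.9% of the genes tested, where chance gives 20% for a single gene. Genes moved together between libraries, with 72.9% of the variance on the first principal component. The share of 68.9% therefore cannot be tested against 20%. At least 2-fold changes were called for 1654 genes, 990 up and 664 down, and for 1675 with the libraries separate. IFIT2, an interferon-induced inhibitor of translation, went from 2.28 ± 0.20 FPKM (SD, n = 3) to 200 ± 25 FPKM (SD, n = 2), a log2 fold change of 5.93 (SE 0.16, adjusted p = 2.0e-05). SAMD9 rose by 5.27 on the log2 scale, the chemokine CXCL10 by 4.61, RSAD2 (viperin) by 4.37, IFIT3 by 4.28, the interferon gene IFNL1 by 4.06 and IFI44 by 4.01. RARRES3, SAMD9L, TRIM22 and CFB, which encodes complement factor B, rose by between 3.62 and 3.91. SCGB1A1, a secretoglobin, was at 11.8 FPKM on average in the controls and was listed at 0 in the 3 RBP2 libraries. CLIC3 had a log2 fold change of -3.21, the locus of the imprinted H19 RNA and MIR675 one of -3.19, the keratin gene KRT4 one of -3.07 and PDZK1, an estrogen-induced gene, one of -2.93. SCIN, UPK2, ANXA6 and DEGS2 lay between -2.45 and -2.27. RPPH1, the RNA component of RNase P, lay at -2.27, with 47.5, 105 and 214 FPKM in control libraries 1, 2 and 3. As the libraries were poly(A)-selected, its value is uncertain if this RNA lacks a poly(A) tail. HLA-DRB5 at -2.63 and HLA-DRB1 at -2.22 are near-identical class II genes that reads can share, so their values are uncertain.

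**Figure D1:**
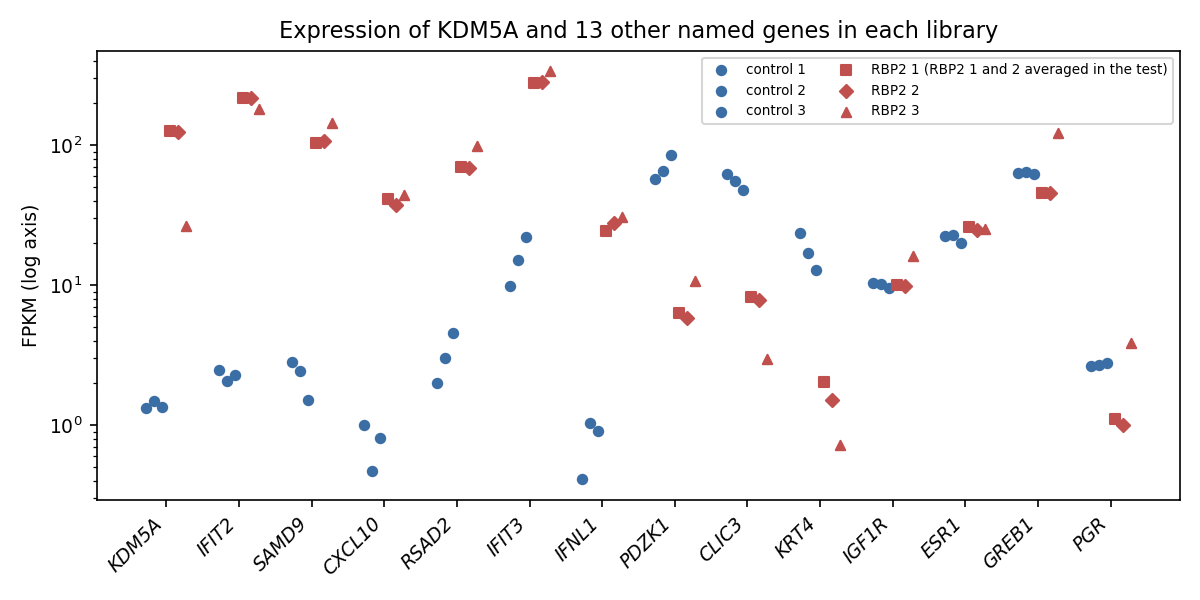
FPKM of 14 named genes in each library, on a log axis, with blue circles for the 3 control libraries and red squares, diamonds and triangles for RBP2 libraries 1, 2 and 3. KDM5A was at 26.5 FPKM in RBP2 library 3 and at 126 and 125 in RBP2 libraries 1 and 2, whereas SAMD9 was at 143 FPKM in RBP2 library 3 and averaged 105 FPKM in RBP2 libraries 1 and 2.

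The number of called genes depended on single libraries and on sequence composition. Without RBP2 library 3, 1 RBP2 sample remained and 289 genes were called; without RBP2 libraries 1 and 2 together the count was 450, and without control library 2 it was 1866. In these libraries the deviation from the gene mean correlated across genes with transcript GC content, with Spearman's rho of 0.16, 0.55 and 0.62 in control libraries 1, 2 and 3 and of -0.50 in each RBP2 library; genes are not independent replicates. After each library's trend on GC content and transcript length was removed, 3382 of 11244 annotated genes were called, 1686 rising and 1696 falling, and 776 changed at least 2-fold. Without the correction 4396 of the same genes were called, 1527 of them at least 2-fold. Of the 4405 earlier calls with an annotation, 2390 were called in the same direction after the correction and none in the opposite one. Among the 24 genes with the largest changes, IFI44, HLA-DRB5, SCIN, ANXA6, DEGS2, RPPH1 and HLA-DRB1 were not called without RBP2 library 3, and RPPH1 was not called after the correction (adjusted p = 0.053). Of the 119 named genes that were called, 37 were called under each single left-out library, and 82 were not without RBP2 library 3.

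**Figure D2:**
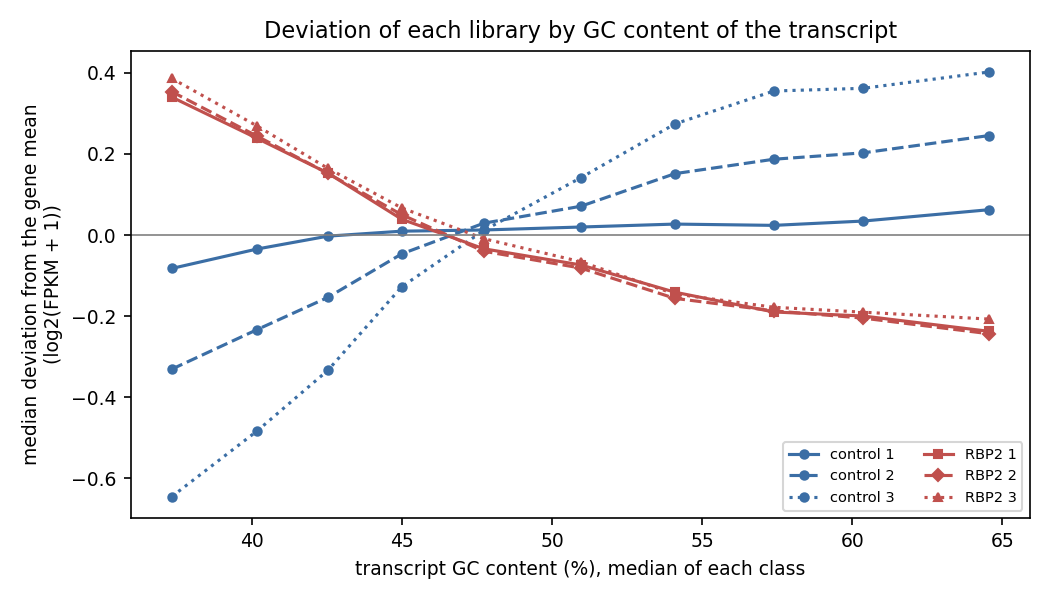
Median deviation of each library from the gene mean, in units of log2(FPKM + 1), for 10 classes of genes by transcript GC content (percent, class medians on the x axis). Blue lines are the 3 control libraries and red lines the 3 RBP2 libraries; in the class with the lowest GC content control library 3 lay at -0.64 and RBP2 library 3 at 0.39.

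Of the 36 interferon-stimulated genes tested, 26 rose and none fell. Adjusted over the list alone 29 rose, as did 29 with the 6 libraries separate. The sensors of viral RNA rose, with log2 fold changes of 2.63 (SE 0.14, adjusted p = 3.2e-04) for DDX58, which encodes RIG-I, and of 3.20 (SE 0.20, adjusted p = 6.1e-04) for IFIH1, which encodes MDA5. The transcription factor gene STAT1 rose by 1.75 and OASL by 3.51. The values of IFI27 (-0.68), IFITM2 (0.12), IFITM3 (0.010) and TMEM173 (0.0070) were not called, with adjusted p between 0.39 and 0.99. The list's median log2 fold change was 1.81 and camera called it upward (adjusted p = 3.1e-14), but not with an estimated correlation between its genes (adjusted p = 0.65 with an estimated correlation). After the GC and length correction 32 members rose and the median was 2.04. Of 12 antigen presentation genes, 11 rose, and 12 did when adjusted over the list alone or with the 6 libraries separate. B2M, the light chain of MHC class I, went from 410 ± 40 to 1543 ± 100 FPKM (SD, n = 3 and 2), TAP2, a peptide transporter subunit, rose by 1.88 on the log2 scale, NLRC5, an activator of class I genes, by 1.99, and HLA-B, whose reads can be shared with other class I genes, by 2.02. Camera called this list upward (adjusted p = 2.2e-06; adjusted p = 0.65 with an estimated correlation). Without RBP2 library 3, 16 interferon-stimulated and 3 antigen presentation genes were called, all rising, and the counts were the same without RBP2 libraries 1 and 2.

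**Figure D3:**
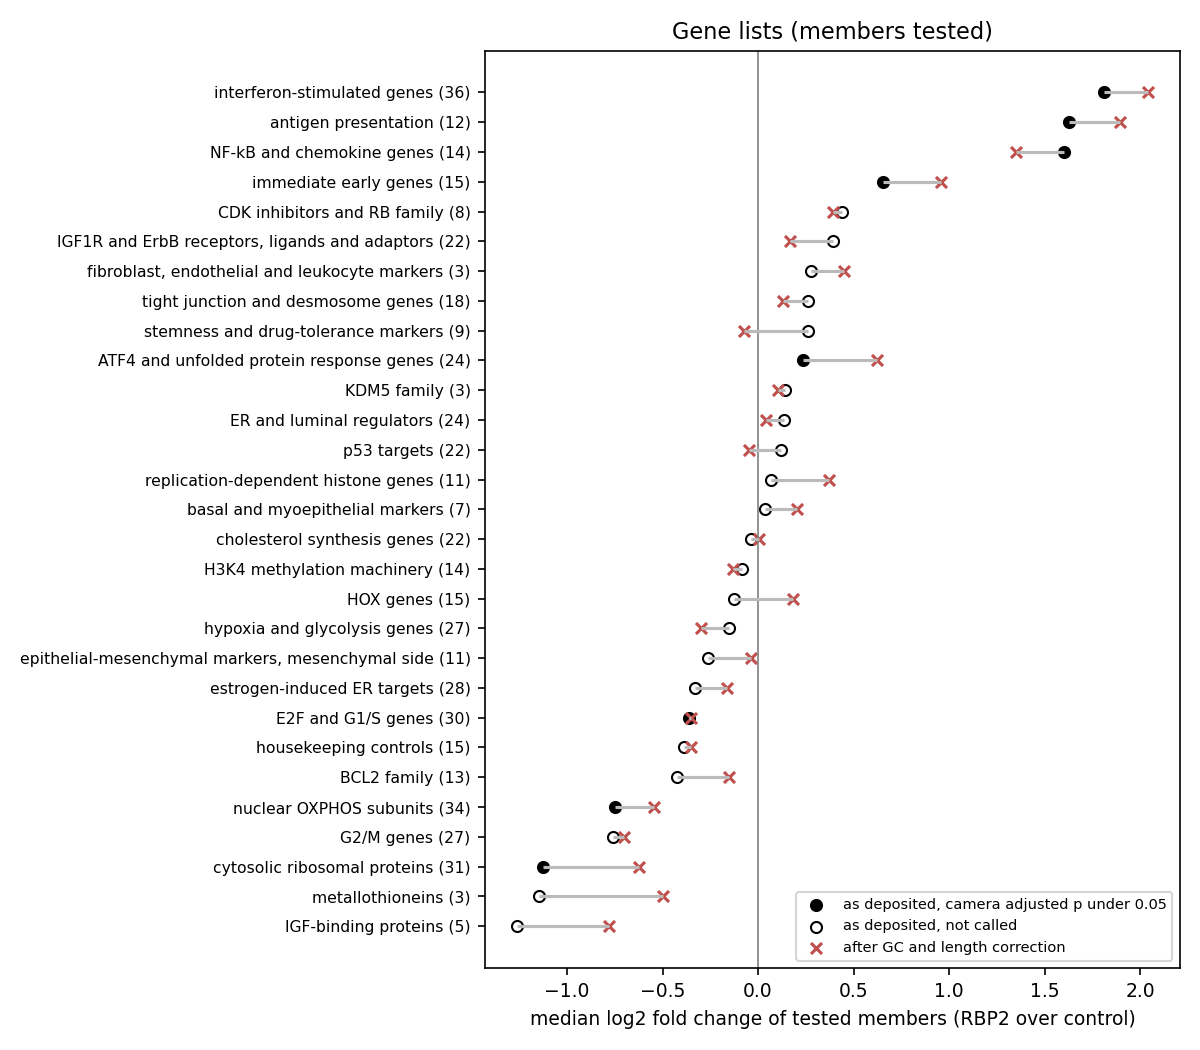
Median log2 fold change (RBP2 over control) of the tested members of 29 gene lists, with the number tested in brackets. Filled circles are lists called by camera with a preset correlation, open circles are lists not called, and red crosses are the medians after the GC and length correction; the interferon-stimulated genes moved from 1.81 to 2.04 and the cytosolic ribosomal proteins from -1.12 to -0.62.

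Of 14 NF-kB and chemokine genes, 12 rose, all 14 did when adjusted over the list alone, and 13 did with the 6 libraries separate. TNFAIP3, a feedback inhibitor of NF-kB, rose by 2.49 on the log2 scale (SE 0.16, adjusted p = 6.1e-04) and CXCL8, listed as IL8, by 3.51 (SE 0.24, adjusted p = 9.0e-04). CCL20 was listed at 0 in the controls and averaged 2.69 FPKM in RBP2 cells. The camera adjusted p was 6.1e-09, and 0.49 with an estimated correlation. Of 15 immediate early genes, 7 rose and none fell, and 8 rose when adjusted over the list alone or with the 6 libraries separate. They included ATF3 (2.41), KLF6 (1.16), JUN (0.95) and JUNB (0.70), with a camera adjusted p of 0.0041, and an adjusted p of 0.56 with an estimated correlation. Of 24 ATF4 and unfolded protein response genes, 7 rose and 1 fell, over all genes and adjusted over the list alone, and 16 were not called; with the 6 libraries separate 10 rose and 2 fell. SLC7A11, a cystine transporter, rose by 2.52, and ATF3, which both lists hold, and the chaperone gene DNAJB9 by 2.41 and 2.48. PHGDH, an enzyme of serine synthesis, had a log2 fold change of -1.81. The list's camera adjusted p was 0.042, and 0.83 with an estimated correlation; without control library 1 it was 0.15, and without RBP2 libraries 1 and 2 it was 0.28. DNAJB9 and ATF3 differed within the RBP2 group, at 98.7 and 43.2 FPKM in the averaged RBP2 libraries 1 and 2 and at 37.2 and 18.7 FPKM in library 3. Without RBP2 library 3, 9 NF-kB and chemokine genes, 1 immediate early gene and 6 ATF4 and unfolded protein response genes were called. Without control library 2, 3 immediate early genes were called and JUNB was not; without RBP2 libraries 1 and 2, 1 immediate early gene rose, and 4 ATF4 and unfolded protein response genes rose and 1 fell. After the correction 11 of the latter list rose and 1 fell.

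Of 30 E2F and G1/S genes, 12 fell and 1 rose, and 13 fell when adjusted over the list alone; with the 6 libraries separate 18 fell and 2 rose. The uracil-DNA glycosylase gene UNG had a log2 fold change of -1.18 (SE 0.20, adjusted p = 0.010), and the replication genes GINS2, MCM2 and CDT1 lay at -1.28, -1.10 and -1.16, whereas CCNE2, which encodes cyclin E2, rose by 1.30. Camera called the list downward (adjusted p = 8.9e-04; adjusted p = 0.65 with an estimated correlation). Of 27 G2/M genes, 14 fell and 2 rose, and adjusted over the list alone 14 fell and 3 rose. With the 6 libraries separate 16 fell and 4 rose. BIRC5 (survivin) was at -1.38, FOXM1 at -1.32, AURKB at -1.25 and PLK1 at -1.43, whereas CENPE rose by 1.26 and the proliferation marker MKI67 by 0.95. The G2/M list was not called (camera adjusted p = 0.052; adjusted p = 0.84 with an estimated correlation). It was called downward with the 6 libraries separate (adjusted p = 0.031), after the GC and length correction (adjusted p = 3.9e-04), when 15 members fell and none rose (adjusted p = 0.79 with an estimated correlation), and without control library 2, control library 3 or RBP2 library 3 (adjusted p = 0.038, 0.020 and 7.4e-04), but not without RBP2 libraries 1 and 2 (adjusted p = 0.36). Of 34 nuclear-encoded subunits of oxidative phosphorylation, 24 fell and 1, COX6C, rose, 26 fell when adjusted over the list alone, and 28 fell with the 6 libraries separate. NDUFS7 was at -1.19, NDUFB5 at -0.75, COX5B at -1.13 and COX5A at -1.02 (camera adjusted p = 8.7e-07; adjusted p = 0.75 with an estimated correlation). Of 31 cytosolic ribosomal protein genes, 29 fell and none rose, and 30 fell when adjusted over the list alone or with the 6 libraries separate. RPS6 went from 3919 ± 710 to 1487 ± 9.5 FPKM (SD, n = 3 and 2), and RPS23, RPL13 and RPL3 had log2 fold changes of -1.06, -1.44 and -1.20; reads of this family can be shared with its pseudogenes. The camera adjusted p was 9.0e-10, and 0.67 with an estimated correlation. Ribosomal protein genes held 27.97%, 28.3% and 29.7% of the summed FPKM in control libraries 1, 2 and 3 and 19.4% to 19.7% in RBP2 libraries. After the correction, 23 ribosomal and 17 of 30 annotated oxidative phosphorylation genes fell. Of the E2F and G1/S genes, 11 then fell and none rose, so CCNE2 was not called upward. Without RBP2 library 3, 1 G2/M gene and none of the E2F and G1/S, oxidative phosphorylation or ribosomal genes passed the limma test; without control library 2, 8, 6, 7 and 12 genes of these lists fell. None of them was called without RBP2 libraries 1 and 2, and 5 G2/M and 2 E2F and G1/S genes rose without control library 1.

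ESR1, which encodes the estrogen receptor, was not called, at 21.7 ± 1.5 FPKM in control and 25.2 ± 0.3 FPKM in RBP2 samples (SD, n = 3 and 2; adjusted p = 0.27). Of 24 ER and luminal regulators, 7 rose and 5 fell, and 8 and 6 when adjusted over the list alone or with the 6 libraries separate. The corepressor gene NRIP1 rose by 1.57 on the log2 scale and AGR2 by 1.75, whereas the luminal keratin genes KRT18 and KRT8 had log2 fold changes of -1.52 and -1.38 (camera adjusted p = 0.62). None of the list was called without RBP2 library 3, 1 fell and none rose without RBP2 libraries 1 and 2, and 3 rose and 2 fell without control library 2. Of 28 estrogen-induced genes, 2 rose and 7 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.28; adjusted p = 0.84 with an estimated correlation); 2 rose and 11 fell with the 6 libraries separate. PDZK1, FKBP4 and SIAH2 were at -2.93, -1.11 and -1.16, and AREG, which encodes the ErbB ligand amphiregulin, rose by 1.85. The classical targets PGR (-0.23, adjusted p = 0.60), GREB1 (0.23, adjusted p = 0.62) and TFF1 (0.29, adjusted p = 0.55) were not called, although TFF1 was after the correction (0.98, adjusted p = 0.038), and PGR was with the correction and the 6 libraries separate (-1.04, adjusted p = 0.034). GREB1 stood at 45.3 FPKM in the averaged RBP2 libraries 1 and 2, at 122 in RBP2 library 3 and at 63.1 ± 0.9 FPKM (SD, n = 3) in the controls. PGR stood at 1.06 FPKM in the averaged RBP2 libraries 1 and 2. In RBP2 library 3 it was at 3.89 FPKM, above the controls at 2.64 to 2.79 FPKM. Without RBP2 library 3, 1 estrogen-induced gene, PDZK1, fell and none rose, FKBP4, SIAH2 and AREG were not called, and the list was called downward with the preset correlation (camera adjusted p = 0.0068), and without RBP2 libraries 1 and 2 1 gene rose, 1 fell and the adjusted p was 0.87. Without control library 1, 11 genes of this list fell, and 1 rose without control library 2 or control library 3.

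Of 22 genes for the IGF1R and ErbB receptors, their ligands and adaptors, 7 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.10), and 10 and 4 with the 6 libraries separate. The ErbB ligand genes AREG, also counted among the estrogen-induced genes, and HBEGF rose by 1.85 and 1.28, the insulin receptor substrate gene IRS2 by 0.62 and the kinase subunit gene PIK3CA by 0.96. IGF1R itself was not called (0.32, SE 0.21, adjusted p = 0.26), at 9.98 FPKM in the averaged RBP2 libraries 1 and 2, 16.1 in RBP2 library 3 and 9.99 ± 0.44 FPKM (SD, n = 3) in the controls. EGFR was at 0.47 (adjusted p = 0.043), ERBB2 at -0.52 (adjusted p = 0.046) and ERBB3 at -0.43 (adjusted p = 0.074). ERBB3 was called with the 6 libraries separate (-0.37, adjusted p = 0.044) and without control library 1 (-0.49, adjusted p = 0.047). After the GC and length correction 3 members rose and 1 fell, 3 rose and none fell without control library 2, 1, HBEGF, rose without RBP2 library 3, and none was called without RBP2 libraries 1 and 2. Without control libraries 1 and 3 in turn, 4 and 1 fell. After the correction EGFR, ERBB2 and PIK3CA (0.010, adjusted p = 0.96) were not called. EGFR and ERBB2 were also not called without control library 2, control library 3 or RBP2 library 3, with adjusted p up to 0.19 and 0.21, nor was EGFR without control library 1. Of 5 IGF-binding protein genes, each was called, also adjusted over the list alone and with the 6 libraries separate: IGFBP3 and IGFBP6 rose by 1.91 and 1.14, and IGFBP2, IGFBP5 and IGFBP4 had log2 fold changes of -1.76, -1.65 and -1.26 (camera adjusted p = 0.69). IGFBP4 was not called after the correction (-0.78, adjusted p = 0.11), and none of the 5 was without RBP2 library 3. Without RBP2 libraries 1 and 2, 1 rose and 1 fell.

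Camera called none of the other lists. Among 14 genes of the H3K4 methylation machinery 3 rose, namely KDM6A (1.17), KMT2A, listed as MLL (1.16), and KMT2C, listed as MLL3 (1.30), and 4 fell, among them WDR5 (-0.69); the list's median was -0.083 and its mean 0.092, with an upward camera direction. In the BCL2 family of 13 genes 4 rose, including PMAIP1 (2.31) and MCL1 (0.87), and 6 fell, including BOK (-1.15) and BIK (-0.87); after the correction 4 rose and 1, BOK, fell. Of 8 CDK inhibitor and RB family genes, RB1 (0.88) and CDKN1B (0.54) rose and CDKN2C (-0.86) fell. Of 22 p53 targets 6 rose, including GADD45A (1.82) and GDF15 (1.19), and 5 fell, including FDXR (-1.31) and TP53I3 (-1.10). Of 27 hypoxia and glycolysis genes 4 rose, among them ADM (7.57 to 23.2 FPKM), VEGFA (10.5 to 31.2 FPKM) and HK2 (log2 fold change 1.61), and 9 fell, among them the lactate transporter gene SLC16A3 (-1.77). Cholesterol synthesis genes split into 7 that rose and 6 that fell of 22, with HMGCS1 (1.09), IDI1 (1.09), LDLR (0.73) and STARD4 (0.89) among the former; STARD4 was at 0.0060 after the correction. Their median was -0.038 and their mean 0.021, with an upward direction. Of 18 tight junction and desmosome genes 4 rose, including DSP (1.31) and OCLN (0.82), and 2 fell, CLDN3 (-1.44) and TJP3 (-0.86). Of 11 mesenchymal markers 3 fell, TNC (-1.48), TAGLN (-1.36) and ACTA2 (-1.44), and 3 rose, including FN1 (0.68). SOX9 (1.38) and KLF4 (1.95) rose among 9 stemness and drug-tolerance markers. Among 11 replication-dependent histone genes HIST1H4H (2.22) and HIST1H2BC (1.04) rose. That list was called upward after the GC and length correction (camera adjusted p = 0.0049, and 0.67 with an estimated correlation). The libraries were poly(A)-selected, so values of histone transcripts without a poly(A) tail are uncertain. Of 15 HOX genes HOXB3 (0.66) rose and HOXC11 (-0.68), HOXC10 (-0.72) and HOXC12 (-0.63) fell. Among 7 basal markers LAMC2 (1.54) rose and ACTA2 and CAV1 (-1.42) fell, with a median of 0.038, a mean of -0.094 and a downward direction. Of 3 metallothionein genes MT1F (-1.43) and MT1X (-1.15) fell. Of 3 tested markers of fibroblasts, endothelium and leukocytes, CD68 rose (1.62). Of 15 housekeeping genes 6 fell, among them RPLP0 (-1.35), PPIA (-1.05) and SDHA (-0.78), and 1, B2M (1.91), rose. Adjusted over the list alone, 3 CDK inhibitor and RB family genes rose and 1 fell, 4 BCL2 family genes rose and 7 fell, 1 HOX gene rose and 1 fell, 5 hypoxia and glycolysis genes rose and 12 fell, 8 cholesterol synthesis genes rose and 8 fell, and 1 housekeeping gene rose and 7 fell; the counts of the other lists in this paragraph stayed as over all genes. With the 6 libraries separate the numbers rising and falling were 4 and 4 for H3K4 machinery, 4 and 7 for BCL2 family, 4 and 1 for CDK inhibitor and RB family, 7 and 6 for p53 target, 6 and 12 for hypoxia and glycolysis, 9 and 10 for cholesterol synthesis, 7 and 3 for tight junction and desmosome, 3 and 4 for mesenchymal, 2 and 1 for stemness, 4 and 0 for histone, 1 and 5 for HOX and 2 and 7 for housekeeping genes, and for the other lists as with 5 samples. After the GC and length correction 8 hypoxia and glycolysis genes rose and 5 fell, 2 HOX genes rose and 1 fell, 5 cholesterol synthesis genes rose and 2 fell, 1 tight junction and desmosome gene rose and 2 fell, and 2 H3K4 machinery genes rose and 2 fell. The camera direction turned upward for the hypoxia and glycolysis, HOX, BCL2 family and basal lists and downward for the H3K4 list, none of them called, and the HOX median went from -0.13 to 0.18. After the correction BIK, RB1, TP53I3, STARD4, OCLN, HOXC10, HOXC12, MT1F and MT1X were not called, the adjusted p being 0.27 for RB1, 0.31 for OCLN and 0.066 for TP53I3. Of the genes named in this paragraph, those called without RBP2 library 3 were PMAIP1, GADD45A, ADM, VEGFA, TNC, TAGLN, ACTA2, KLF4, HIST1H4H, LAMC2 and B2M. Without control library 2 no HOX gene and no CDK inhibitor or RB family gene was called, 1 BCL2 family gene rose and 1 fell, 3 cholesterol synthesis genes rose and none fell, 4 hypoxia and glycolysis genes rose and 1 fell, 3 p53 targets rose and 2 fell, 2 tight junction and desmosome genes rose and 1 fell, 3 H3K4 machinery genes rose and none fell, 3 mesenchymal markers fell and none rose, 1 metallothionein gene fell, and 1 housekeeping gene rose and 1 fell. Without control library 3, 2 H3K4 machinery genes and 1 HOX gene fell, 4 cholesterol synthesis genes rose, 2 housekeeping genes rose and 1 stemness marker fell. Without control library 1, 10 cholesterol synthesis genes fell, 4 CDK inhibitor and RB family genes rose and 1 histone gene fell. No mitochondrially encoded transcript was tested. The camera adjusted p of these lists lay between 0.21 and 0.96.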

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

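Chosen after the data were examined were the averaging of RBP2 libraries 1 and 2, the GC and length correction with all its variants, the fit without RBP2 libraries 1 and 2, and the fit on annotated genes only. KDM5A was called in each of the 25 other fits run, with a log2 fold change from 3.52 (without RBP2 libraries 1 and 2) to 5.72 (without RBP2 library 3). Single left-out libraries moved the number of called genes between 289 and 6225, those that rose between 236 and 3049, those that fell between 53 and 3176, and those with at least 2-fold changes between 286 and 2360. The lowest came without RBP2 library 3, where the lone RBP2 sample is assumed to vary like the controls; fewer samples are part of the cause. Without control library 2 the counts were 1866, 1090 rising and 776 falling, and without control library 3 the 2-fold count was 1096; the cause was not tested. Without RBP2 libraries 1 and 2 together the counts were 450, 279, 171 and 437. No gene called with 5 samples was called in the opposite direction under the alternatives fixed beforehand; after the GC and length correction 6 were with the 6 libraries separate, 4 with these and the block, and 2 with control library 1 left out. With GC content and length corrected the 2-fold count was 776, against 1527 for the same genes uncorrected. Where the libraries changed too, it was 811 with the 6 libraries separate, 818 with these and the replicate block, 989 with control library 1 left out and 586 with control library 3 left out; uncorrected, over all genes tested, these gave 1675, 1679, 2360 and 1096. With that last setting 2368 genes were called, 1229 rising and 1139 falling. The 6 libraries kept separate gave 6833 calls, and 6375 with the replicate number as a block. Same-numbered deviations correlated at 0.046, -0.092 and 0.027, which gives no sign of pairing by number. Pairing is not excluded, since the deviations were centred within each group and RBP2 libraries 1 and 2 are nearly the same. Of 8 lists called, 0 remained with an estimated correlation. The size of the correlation does not account for this in the immediate early genes. Their estimate was -0.021, below the preset 0.01, yet their camera adjusted p rose from 0.0041 to 0.56. The estimates of the other called lists lay between 0.065 and 0.60. The loss of calls therefore cannot show whether correlation between genes produced them. In every fit other than that with an estimated correlation, 7 of the 8 were called. The exception was the ATF4 and unfolded protein response list, lost without control library 1 and without RBP2 libraries 1 and 2. Over single left-out libraries 7 to 10 lists were called. Where a gene was called in either of the fits compared, the sign turned for KDM5B (-0.27, adjusted p = 0.029) and PIK3CA (-0.035) after the correction with 6 libraries, for PIK3CA also with the block (-0.035), and for STARD4 (-0.12) after the correction without control library 1; the cause was not tested. Signs also turned without a call in either fit: KDM5B (-0.29) and ESR1 (-0.032) after the correction, GREB1 (-0.47), TFF1 (-0.039), IGF1R and KDM5C with 1 library left out, GREB1 also with the 6 libraries separate, and PGR (0.40) without RBP2 libraries 1 and 2. Of the 119 named calls the correction ended 13, and MLL, MLL3, IL8 and H19 with MIR675, which lack an annotation, were not tested after it. Scaling moved the median of all genes by at most 0.03. The read depth behind each value is unknown.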

Other observations

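The tests in this part were chosen after the data were seen. Of 8 interferon genes examined, IFNB1 and the lambda interferon genes IFNL1, IFNL2 and IFNL3 rose in RBP2 cells. IFNB1 stood at 0, 0.422 and 0.465 FPKM in the controls and at 8.44, 9.56 and 23.5 FPKM in RBP2 libraries 1, 2 and 3 (limma log2 fold change 3.62, adjusted p = 0.0027), and IFNL2 and IFNL3 rose by 3.27 and 3.19, while IFNA1, IFNG, IFNK and IFNE were listed at 0 in all 6 libraries. The checkpoint ligand gene CD274 rose by 1.26 (adjusted p = 0.0042), from 0.0445 to 1.51 FPKM, and the transcription factor gene IRF1 by 1.45 (adjusted p = 0.0062). The receptor subunit gene IFNAR2 had a log2 fold change of -0.87 (adjusted p = 0.011). The receptor genes IFNAR1 (0.39, limma adjusted p = 0.11) and IFNLR1 (-0.17, limma adjusted p = 0.36), also examined, were not called. The double-stranded RNA sensor gene TLR3 rose by 1.42 (adjusted p = 0.0094), but not after the GC and length correction (0.69, adjusted p = 0.095). PTPRC, CD3E and CD19, which mark leukocytes, were at or below 0.215 FPKM in all libraries, and CD14 averaged 0.0530 FPKM in control and 0.193 FPKM in RBP2 samples. CD68, a macrophage marker and the 1 called gene of the list of fibroblast, endothelial and leukocyte markers, rose from 2.25 to 8.84 FPKM (log2 fold change 1.62, adjusted p = 0.010; 2.06 after the correction), but was not called without RBP2 library 3.

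The values in RBP2 library 3 are set here beside the mean of RBP2 libraries 1 and 2. With 1 sample on each side, no spread between samples stands behind the differences, and the percentiles rank lists of genes only. PGR was 3.66 times, WISP2 4.43 times and GREB1 2.68 times as high in library 3 as in the mean of libraries 1 and 2, and in each of these genes the controls lay in between. The median difference of the 28 estrogen-induced genes was 0.53 on the log2 scale, at percentile 100 among 10000 random lists matched on expression. That of the G2/M genes was 0.49, also at percentile 100, and that of the ATF4 and unfolded protein response genes was -0.37, at percentile 0. The HOX genes (0.36) and antigen presentation genes (0.32) were both at percentile 99.98, the interferon-stimulated genes (0.16) at 99.66, the mesenchymal markers (0.31) at 99.52, the H3K4 methylation machinery (0.21) at 97.98, the ER and luminal regulators (-0.097) at 1.89 and the immediate early genes (-0.24) at 0.17. IFI27 was 4.13 times as high in libraries 1 and 2 as in library 3.

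The first pattern is the number of called genes, which goes with a trend on GC content and length. The tables argue against this trend as the whole cause, since 2390 of 4405 annotated calls were called in the same direction after it was removed. The 2015 calls that ended had a median absolute log2 fold change of 0.76 before (median SE 0.20) and 0.28 after (median SE 0.14), so they ended because the fold shrank; a technical trend and regulation tied to GC content or length cannot be told apart for these genes, because the trend follows the groups. It also separated the controls, with Spearman's rho of 0.62 across genes between GC content and control library 3 minus control library 1, and the correlation of that difference with RBP2 minus control library 2 was -0.50 before and -0.28 after the correction. For the 6 libraries separate, 1 of the 10 splits into groups of 3, the real one, reached 6833 calls, and the highest other called 2. Each other split mixes control and RBP2 libraries, which places any group difference in the spread within its groups. Low counts there are therefore no separate evidence. Besides, 10 splits are too few for a share under 0.05.

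The second pattern is KDM5A, lower in RBP2 library 3 than in RBP2 libraries 1 and 2. If cells without the construct diluted library 3, other genes would show the share of the change that KDM5A shows, 0.20. That expectation holds only for changes confined to the cells with the construct, which was not tested. Over the 157 genes that moved at least 4-fold in libraries 1 and 2, the median share was 0.91 (quartiles 0.49 and 1.06). This argues against dilution for these genes as a set. For the 41 that fell the median share was 1 (quartiles 0.95 and 1). For the 116 that rose, genes picked for being high in libraries 1 and 2, it was 0.68 (quartiles 0.35 and 1.14). The argument is weaker for the genes that rose. A response that does not scale with the KDM5A transcript and a different population of infected cells were not tested, as the design holds no further expression level.

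The third pattern is the rise of interferon-stimulated genes. The GC and length trend does not account for it, as the list's median log2 fold change was 2.04 after the correction. A rise proportional to the KDM5A transcript is argued against for RBP2 library 3 only. The median share of the rise seen there was 1.17 (quartiles 0.79 and 1.32) over the 27 members at least 2-fold higher in libraries 1 and 2. That choice leaves out library 3. Over all 36 members the median share was 1.08 (quartiles 0.70 and 1.34), beside 0.20 for KDM5A. With 1 library at that KDM5A level, how the response scales with KDM5A in general cannot be decided. RBP2 overexpression stays open as an explanation, as does a response to infection or culture that differed between the populations; neither was tested, since the labels do not say how many infections each group comes from.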
